A study of Homo sapiens with 14 samples.

How the data were processed

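RNA from 14 samples of OVCAR4 cells was sequenced with the BGI platform's standard protocol, per the labels. Per the labels, 300000 cells were reverse transfected with 120 nM of siRNA, given fresh medium after 24 hours and harvested for total RNA after 72 hours. The siRNAs were Dharmacon ON-TARGETplus pools, whose guide sequences are not given. Libraries were grouped by the pool named in each sample title, which gave 7 groups of 2, with siNT1 and siNT2 as controls. The labels do not say whether the 2 libraries of a group came from separate transfections, so every p-value measures only the spread between these libraries.

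The deposited values were whole-number read counts per gene, not normalised, on genome build hg38. The authors named STAR 2.5.1b and featureCounts 1.6.3 without saying how they were run, and the annotation release, the strand setting and any filter are not stated. Of the 58219 genes in the table, 57881 matched GENCODE 29 by identifier, 57879 of them at an overlapping position, and names and positions were taken from there. Since the strand is not known, reads of overlapping or antisense genes cannot be told apart. A further column held gene length as summed exons, and it was not used in a test. Genes with 0 counts in all libraries numbered 19115.

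Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 21032. Libraries were scaled by the trimmed mean of M-values (TMM), and CPM values were computed on the scaled library sizes. A single edgeR quasi-likelihood model held a coefficient for each of the 7 groups, with 7 residual degrees of freedom, a common dispersion of 0.00573 and a biological coefficient of variation of 7.6%. Each knockdown was compared with the mean of siNT1 and siNT2. The control pools were compared with each other, siDual with each single knockdown, and siPAX8 with siSOX17. Additivity was tested as siDual minus siPAX8 minus siSOX17 plus the control mean on the log2 scale. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. A standard error is the log2 fold change over the square root of the quasi-likelihood F. Within a group, values are mean ± SD over its libraries.

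Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The 38 lists cover lineage, proliferation, stress, signalling, metabolism, matrix and cell type markers, and come from general knowledge. Beside each list stand the members called over all genes and the members called when p-values were adjusted over the list alone. With the correlation estimated from the data, the camera calls that held were the G1/S and EMT lists in siPAX8, siSOX17 and siDual, and the G2/M list and angiogenesis regulators in siPAX8. In the additivity comparison the G1/S, G2/M, EMT, angiogenesis and MAPK feedback lists held. The test fry was run as an alternative: its directional p asks whether a list's genes move on balance in the same direction, and its mixed p whether they change in either direction. Neither compares a list with other genes.

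The genes named were set by rule. PAX8, SOX17, MECOM and WT1 were taken in every comparison. For each knockdown against the controls, protein-coding genes with a mean log2 CPM of at least 1 and both knockdown libraries beyond all 4 control libraries on the same side were ranked, and the 10 largest called increases and 10 largest called decreases were taken. From each list came at most 2 called members with the largest increase and 2 with the largest decrease. For the other comparisons the 5 largest in each direction were taken, and fewer are named in places. Some genes that the rule takes are not reported here, and the counts and list tests include them. The comparisons, lists, naming rule and alternatives were fixed before the data were examined, except the fit without mitochondrially encoded genes and the lists without the targeted genes, which were chosen after seeing the data. The search for sequence matches was also planned after the gene comparisons had been seen.

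Correlations of responses were taken across genes and compared with 20 simulations of unchanged groups that share the control libraries, in which 0.4 genes on average were called. Ratios of low counts carry exact 95% intervals, which cover counting error only. Sequence matches were searched in 3' UTRs of at least 50 bases for 11687 of 12023 genes considered. Each of 16221 heptamers found in at least 50 genes was tested by regression of the log2 fold change on its presence, UTR length, GC content and expression level, beside 100 permutations of the genes. Effects added to simulated data were recovered in 70 to 82% of genes at 2-fold and 86 to 96% at 4-fold, with 5 to 14 false calls among 20801 or 20832 unchanged genes. The alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter, a filter of 1 CPM in 4 libraries, a block for the replicate number, the compared groups alone, each control pool alone, the controls as 1 group, each library left out, and a 2-fold threshold. The replicate number was not used in the comparisons reported. The residuals of like-numbered replicates correlated above 0.1 in 7 of 21 pairs of groups and from -0.018 to 0.161 over all. The only value below 0 was that of siNT2 with siMECOM (-0.018). A weak effect shared by like-numbered replicates is therefore not excluded, and the block was run as an alternative for that reason. Software was R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No library was left out.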

Results

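RNA abundance was measured by sequencing in OVCAR4 cells, an established human high-grade serous ovarian cancer cell line, 72 hours after reverse transfection with pools of small interfering RNAs (siRNAs). An siRNA directs the degradation of a matching transcript. The 14 libraries fell into 7 groups of 2. The groups siNT1 and siNT2 received separate non-targeting control pools. Another 4 groups received a pool against PAX8, SOX17, MECOM or WT1, and the group siDual received the PAX8 and SOX17 pools together. Going by its title, the series asks which transcription factors act as master regulators of a cancer type, and these 4 genes encode the factors whose loss it examined in this line. The gene counts summed to 40832825 to 49059114 in the 4 control libraries and to 41107918 to 49803860 in the 10 knockdown libraries. Between 27628 and 29311 genes per library had at least 1 count.

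The targeted transcripts were lower in the groups named for them. PAX8 (ENSG00000125618.16), which encodes a paired-box factor of Mullerian, thyroid and kidney development, lies on the minus strand of chromosome 2 at 113215997 to 113278950 (hg38). Its level was 204.8 ± 14.7 CPM (read counts scaled to library size; SD, n = 4) in the control libraries, 35.5 ± 3.88 (SD, n = 2) in siPAX8 and 51.7 ± 1.57 in siDual. The log2 fold changes were -2.52 ± 0.08 (SE; adjusted p = 2.32e-14) and -1.98 ± 0.08 (adjusted p = 1.71e-13) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the test used for every gene here. SOX17 (ENSG00000164736.5, chromosome 8 at 54457935 to 54460888), which encodes an SRY-box factor of endoderm and the female reproductive tract, stood at 110.6 ± 7.41 CPM in the controls. It was 14.4 ± 1.83 CPM in siSOX17 (log2 fold change -2.94 ± 0.11, adjusted p = 1.21e-13) and 16.8 CPM in siDual (log2 fold change -2.72 ± 0.11, adjusted p = 1.68e-13). MECOM (ENSG00000085276.17, chromosome 3 at 169083499 to 169663618), which encodes the zinc-finger factor EVI1, fell from 129.9 ± 3.42 CPM to 12.6 ± 5.42 CPM in siMECOM (log2 fold change -3.36 ± 0.16, adjusted p = 8.04e-12). Replicate 1 of siMECOM stood at 8.76 CPM and replicate 2 at 16.4 CPM.

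WT1 (ENSG00000184937.13, chromosome 11 at 32387775 to 32435630), which encodes a zinc-finger factor of kidney and gonad, was near the detection floor before any knockdown. Its control level was 0.394 ± 0.0451 CPM, 75 counts over 4 libraries, and ranked 17560th among the tested genes. The siWT1 libraries held 1 count, 2.41% of the control level with an exact 95% counting interval of 0.0601 to 13.8%. The strand used in counting is not stated, so reads of WT1 and its antisense gene WT1-AS, or of PAX8 and PAX8-AS1, cannot be told apart.

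Some targeted transcripts also changed in groups that received other pools. MECOM fell in siSOX17 (log2 fold change -1.54 ± 0.14) and in siDual (-1.40 ± 0.14), while SOX17 rose to 229.2 ± 15 CPM in siMECOM (1.05 ± 0.09). PAX8 rose in siSOX17 (0.40 ± 0.07) and fell to 114.9 ± 3.65 CPM in siWT1 (-0.83 ± 0.07), and SOX17 fell in siPAX8 (-0.46 ± 0.09). The 3' UTR of PAX8 holds 1 copy of CCACAC, the hexamer described below for genes lower in siWT1. So do 31.6% of the genes not called in siWT1, and CCACACT, the heptamer lowest in siWT1, does not lie in the PAX8 mRNA. The smaller decreases of MECOM in siPAX8 (-0.41 ± 0.13, adjusted p = 0.0116) and in siWT1 (-0.35 ± 0.13, adjusted p = 0.0397) kept their size but not their call. The first was -0.42 without siPAX8 replicate 1 (adjusted p = 0.0533), -0.41 without siPAX8 replicate 2 (0.0587) and -0.41 with DESeq2 (0.103). The second was -0.38 without siWT1 replicate 1 (adjusted p = 0.121), -0.32 without siWT1 replicate 2 (0.181) and -0.34 with DESeq2 (0.193), and leaving out any 1 control library also ended it (adjusted p from 0.0541 to 0.0733). The values of PAX8 in siMECOM (-0.17 ± 0.07, adjusted p = 0.0725) and of SOX17 in siWT1 (0.08 ± 0.09, adjusted p = 0.508) did not pass. WT1, on 6 and 9 counts in siSOX17 and 5 and 8 in siDual, had log2 fold changes of -1.027 ± 0.413 (adjusted p = 0.0436) and -1.308 ± 0.425 (adjusted p = 0.0133). The first kept its direction but lost its call on leaving out any 1 of the 12 libraries of the groups other than siWT1. In those fits it lay between -0.722 (without siSOX17 replicate 1) and -1.389 (without siSOX17 replicate 2). Its call was also lost with DESeq2 (-1.022, adjusted p = 0.183) and against siNT1 (-0.98, 0.0898) or siNT2 alone (-1.074, 0.0619). The call in siDual was lost without siDual replicate 1 (-1.127) or 2 (-1.555) and with DESeq2 (-1.318, adjusted p = 0.0771).

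**Figure D1:**
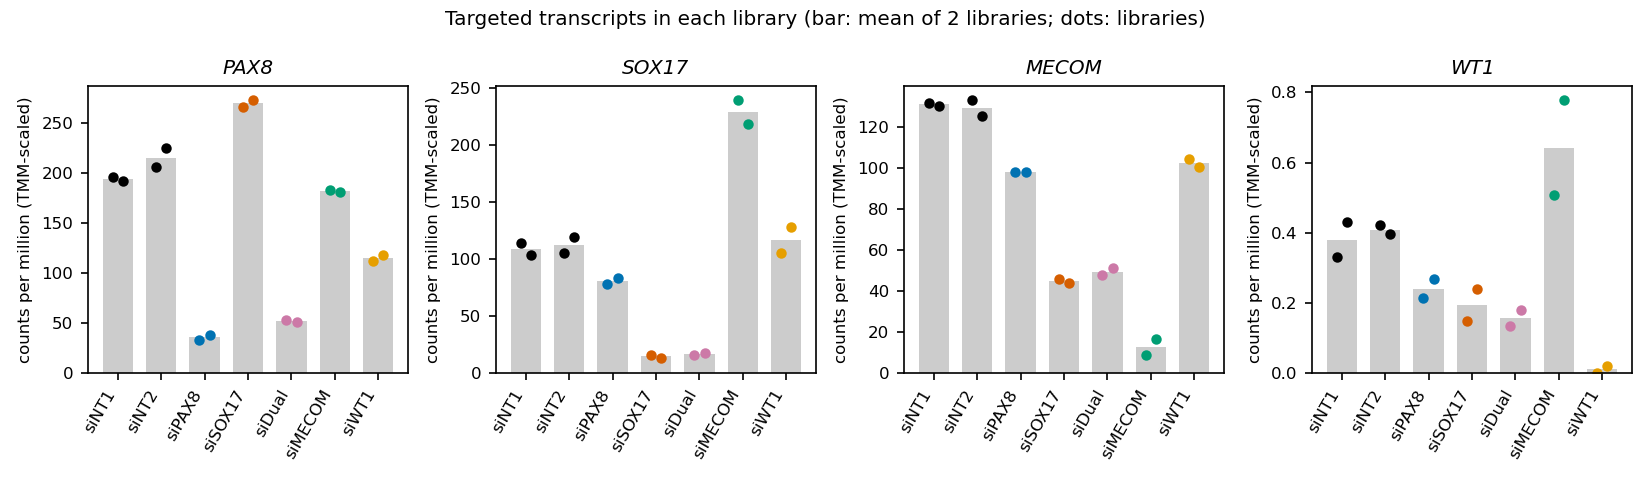
Levels in CPM, scaled by trimmed mean of M-values, of PAX8, SOX17, MECOM and WT1 in each of the 7 groups, with bars at the mean of 2 libraries and dots at the single libraries. PAX8 is lowest in siPAX8 (35.5) and siDual (51.7), SOX17 in siSOX17 (14.4) and siDual (16.8), MECOM in siMECOM (12.6), and the WT1 axis ends below 1.

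Few genes differed between the control pools. Of 21032 genes tested, 51 were higher and 12 lower in siNT1 than in siNT2, 10 of these 63 by at least 2-fold, and 1608 had an unadjusted p under 0.05. Metallothionein genes, which bind zinc and copper, were among the higher ones, with MT1M at a log2 difference of 2.14 ± 0.20 (adjusted p = 1.43e-05), MT1F at 1.16 ± 0.12 and MT1E at 1.14 ± 0.12. SMAP2 was higher in siNT1 (1.18 ± 0.09) and TSPAN2 lower (-1.38 ± 0.15). KRT6A (1.45 ± 0.26, adjusted p = 0.0174) stayed similar in size but lost its call without siNT1 replicate 1 (1.354) or 2 (1.547). The same held without siNT2 replicate 1 (1.268) or 2 (1.653). The count of 63 became 11 and 17 without siNT1 replicate 1 and 2, and 33 and 14 without siNT2 replicate 1 and 2. For siNT1 versus siNT2 it was 150 with replicate as a block, 157 with DESeq2 and 232 without a filter on low counts. Among 38 gene lists, camera called the 28 genes of G2/M and mitosis (median log2 difference 0.07, adjusted p = 0.00979, and adjusted p = 0.823 with an estimated correlation), of which 0 passed the edgeR test singly and 1 did so adjusted over the list alone.

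In siPAX8 the proliferation genes were lower as a group and genes linked to epithelial-mesenchymal transition (EMT) higher. All 29 measured G1/S and DNA replication genes and all 28 G2/M and mitosis genes fell in siPAX8. Of 21032 genes, 5653 were higher and 5336 lower, of which 1687 and 1364 by at least 2-fold. The largest increase was in IL1B, an inflammatory cytokine (log2 fold change 4.33 ± 0.20, from 0.491 to 9.72 CPM). Other large increases were in GJA5, a gap junction connexin (4.17 ± 0.34), SLC28A3, a nucleoside transporter (4.10 ± 0.23), and ANGPTL4, an inhibitor of lipoprotein lipase (4.04 ± 0.13). TMEM40 (3.90 ± 0.17), the protease inhibitor A2M (3.87 ± 0.21), the growth factor FGF1 (3.80 ± 0.17), FOXS1 (3.71 ± 0.20) and ARSJ (3.59 ± 0.15) followed. The largest decreases were in KLHL14, from 25.0 ± 2.78 to 0.496 ± 0.229 CPM (-5.63 ± 0.17), TMEM101 (-5.00 ± 0.40) and the growth factor FGF18, from 69.6 ± 7.94 to 2.46 ± 0.101 CPM (-4.82 ± 0.13). Next were the agmatine hydrolase AGMAT (-4.04 ± 0.26), LRRC61 (-3.69 ± 0.17) and FAM107A (-3.49 ± 0.17). The last of the 10 were the connexin GJB2 (-3.39 ± 0.10), ZBED10P (-3.24 ± 0.15), LRRC41 (-3.18 ± 0.17) and the carbonic anhydrase CA2 (-3.12 ± 0.12). The named genes of this comparison had adjusted p-values of 4.86e-09 or lower.

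Among the cell cycle genes in siPAX8, the replicative helicase subunit MCM6 (log2 fold change -2.96 ± 0.08), the replication clamp PCNA (-2.74 ± 0.07), cyclin A2 (CCNA2, -2.72 ± 0.09) and the anaphase activator CDC20 (-2.32 ± 0.08) fell most. The G1/S list had a median log2 fold change of -1.77 (camera adjusted p = 1.17e-21, and adjusted p = 0.0175 with an estimated correlation). The G2/M list had one of -1.64 (7.9e-22, and adjusted p = 0.0354 with an estimated correlation). Adjusted over the list alone, the same 29 and 28 genes passed. Of 29 ribosome biogenesis and MYC target genes, 20 fell and 0 rose (21 and 0 adjusted over the list alone), among them the genes of the nucleolar proteins NOP56 (-1.20 ± 0.07) and NCL (-1.04 ± 0.07). Camera called this list lower (adjusted p = 1.99e-05, and adjusted p = 0.317 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, rose (1.49 ± 0.10). Of the 24 p53 target genes 11 rose and 8 fell, a list camera did not call (adjusted p = 0.425).

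The EMT genes went the other way. Of 24 such genes, 18 rose and 1 fell in siPAX8 (19 and 1 adjusted over the list alone), among them the matrix protein SPARC (2.34 ± 0.30). The camera adjusted p was 9.6e-06, and adjusted p = 0.0175 with an estimated correlation. Of 37 angiogenesis regulators, 22 rose and 6 fell (23 and 6 adjusted over the list alone, camera adjusted p = 0.000306, and adjusted p = 0.0267 with an estimated correlation), with ANGPTL4 up and FGF18 and the chemokine CXCL1 (-1.82 ± 0.26) down. Camera also called 3 lists higher at adjusted p of 0.00444, 0.0044 and 0.00367, each with adjusted p = 0.0539 with an estimated correlation. They were TGF-beta response genes (15 of 24 higher and 5 lower, TGFB2 2.40 ± 0.09), MAPK feedback and immediate early genes (18 of 27 higher and 5 lower, the EGF receptor ligand HBEGF 3.57 ± 0.09) and squamous keratinocyte markers (7 of 9 higher and 1 lower, KRT6A 3.50 ± 0.18, KRT16 3.29 ± 0.18). YAP and TEAD target genes (13 of 23 higher and 2 lower, tissue factor F3 2.01 ± 0.10, adjusted p = 0.00367, and adjusted p = 0.384 with an estimated correlation) were higher too. So were basement membrane, collagen and integrin genes (15 of 31 higher and 3 lower, ITGA2 3.27 ± 0.16 against ITGB3 -2.46 ± 0.09, adjusted p = 0.0149, and adjusted p = 0.437 with an estimated correlation). The WT1-associated kidney genes were a further such list (9 of 14 higher and 2 lower, WNT4 2.45 ± 0.14, SULF1 2.41 ± 0.10, adjusted p = 0.0239, and adjusted p = 0.124 with an estimated correlation). The counts higher and lower adjusted over the list alone were 15 and 5, 18 and 6, 8 and 1, 13 and 2, 16 and 3, and 9 and 2 in that order. All 13 mitochondrially encoded genes rose (median 0.77, camera adjusted p = 5.31e-05, and adjusted p = 0.437 with an estimated correlation). Ribosomal protein genes were called lower (13 of 40 lower and 0 higher, 11 and 0 adjusted over the list alone, 0.0127, and adjusted p = 0.704 with an estimated correlation), a call lost against siNT1 alone. All genes on the mitochondrial chromosome, which are more than these 13, took 9.80 ± 0.757% of the siPAX8 counts against 5.34 to 6.13% in the 4 control libraries. Ribosomal RNA genes, counted with the mitochondrial ones and with pseudogenes, took 1.47 ± 0.156% against 0.612 to 0.712%. These shares overlap, since both include the mitochondrial ribosomal RNA genes.

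In siSOX17 every measured cell cycle gene of both lists was lower too. The cytokine IL11 rose from 2.15 ± 0.643 to 105.9 ± 13.5 CPM (log2 fold change 5.66 ± 0.11). The natriuretic peptide gene NPPB rose from 10.4 ± 3.95 to 408.4 ± 12.4 CPM (5.35 ± 0.15). Of 21032 genes, 5716 were higher and 5353 lower, of which 1755 and 1314 by at least 2-fold. ANGPTL4 (5.25 ± 0.12), GJA5 (5.13 ± 0.31), the semaphorin SEMA5B (4.70 ± 0.23), the muscle ring-finger gene TRIM55 (4.46 ± 0.22), TMEM40 (4.37 ± 0.17), the GABA transaminase ABAT (3.81 ± 0.12) and FGF1 (3.79 ± 0.17) were also among the largest increases. The cytokine IL33 had the largest decrease, from 2.32 ± 0.192 CPM to 2 counts in both libraries together, 1.1% of the control level with a counting interval of 0.133 to 4%. After it came the forkhead gene FOXQ1 (-4.79 ± 0.33) and the guanylate-binding protein GBP5 (-4.79 ± 0.21). Cyclin A1 (CCNA1, -4.24 ± 0.16), the chemokine CXCL5 (-4.23 ± 0.40), CA2 (-4.21 ± 0.14), IQGAP2 (-4.18 ± 0.16) and SOX5 (-4.01 ± 0.23) were also among the 10 largest decreases. Adjusted p-values of these named genes were 3.51e-08 or lower.

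The 29 G1/S genes fell in siSOX17 with a median of -1.23 (camera adjusted p = 7.91e-17, and adjusted p = 0.0334 with an estimated correlation), among them cyclin E1 (CCNE1, -2.21 ± 0.08) and MCM6 (-1.93 ± 0.08). The 28 G2/M genes fell with a median of -0.81 (3.36e-14, and adjusted p = 0.117 with an estimated correlation). EMT genes rose in 15 of 24 cases and fell in 1 (16 and 2 adjusted over the list alone, camera adjusted p = 2.45e-05, and adjusted p = 0.0334 with an estimated correlation), among them fibronectin (FN1, 3.36 ± 0.17). Wnt response genes fell in 14 of 19 cases and rose in 3, with the Wnt deacylase NOTUM at -3.21 ± 0.19 (camera adjusted p = 0.00204, and adjusted p = 0.117 with an estimated correlation). The basement membrane, collagen and integrin list had 26 of 31 genes higher and 2 lower, with the integrin ITGB6 at 2.65 ± 0.09 (adjusted p = 3.65e-07, and adjusted p = 0.163 with an estimated correlation). The glycolysis and hypoxia list had 27 of 31 higher and 2 lower, with adrenomedullin (ADM) at 2.72 ± 0.09 and the carbonic anhydrase CA9 at 2.54 ± 0.21 (3.65e-07, and adjusted p = 0.197 with an estimated correlation). The epithelial junction list had 17 of 30 higher and 5 lower, with the keratins KRT8 at 1.91 ± 0.11 and KRT18 at 1.90 ± 0.13 (0.00402, and adjusted p = 0.152 with an estimated correlation). For the last 4 of these lists the counts adjusted over the list alone were 3 and 14, 26 and 2, 28 and 2, and 17 and 5 higher and lower.

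Other list changes in siSOX17 included YAP and TEAD targets (17 of 23 higher and 3 lower, adjusted p = 0.00029, and adjusted p = 0.274 with an estimated correlation) and ribosome biogenesis and MYC targets (20 of 29 lower and 3 higher, 0.000543, and adjusted p = 0.353 with an estimated correlation). Antigen presentation genes were higher (9 of 17, the peptide transporter TAP1 1.67 ± 0.09, 0.0335, and adjusted p = 0.425 with an estimated correlation) and endothelial markers lower (6 of 10, 0.0174, and adjusted p = 0.197 with an estimated correlation). Of 37 interferon-stimulated genes, 17 were higher, among them SAMD9L (1.90 ± 0.12), and 7 lower. The list's adjusted p of 0.0417, and adjusted p = 0.545 with an estimated correlation, became 0.0705 against siNT1 alone. MAPK feedback genes had 15 of 27 higher and 6 lower (adjusted p = 0.0436, and adjusted p = 0.184 with an estimated correlation, and 0.053 against siNT1 alone). The counts higher and lower of these 6 lists, adjusted over the list alone, were 18 and 3, 3 and 21, 9 and 0, 0 and 6, 17 and 7, and 15 and 7. Ribosomal protein genes were lower (13 of 40 lower and 0 higher, 9 and 0 adjusted over the list alone, 0.0174, and adjusted p = 0.68 with an estimated correlation), a call that became 0.0702 against siNT1 alone. All 13 mitochondrially encoded genes rose (median 0.91, adjusted p = 2.64e-06, and adjusted p = 0.353 with an estimated correlation). All genes on the mitochondrial chromosome took 10.1 ± 0.163% of the siSOX17 counts, and ribosomal RNA genes, in part the same genes, 1.46 ± 0.054%.

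Transfection of both pools gave the most changed genes. In siDual 6075 genes were higher and 5739 lower than in the controls, of which 1948 and 1591 by at least 2-fold. The connexin GJA5 rose from 0.0979 ± 0.065 to 11.4 ± 1.38 CPM (log2 fold change 6.89 ± 0.26) and ANGPTL4 from 0.877 ± 0.235 to 51.4 ± 0.828 CPM (5.89 ± 0.12). IL11 (5.44 ± 0.11), NPPB (5.36 ± 0.15), TRIM55 (5.27 ± 0.21), TMEM40 (5.24 ± 0.16), FOXS1 (5.09 ± 0.18), the prostaglandin transporter SLCO2A1 (4.47 ± 0.16) and the carboxypeptidase CPA4 (4.47 ± 0.16) were also among the 10 largest increases. The largest decreases were in TMEM101 (-5.60 ± 0.44), FGF18 (-5.45 ± 0.14), CA2 (-4.79 ± 0.15), CXCL5 (-4.44 ± 0.40), CCNA1 (-4.40 ± 0.17), NOTUM (-4.32 ± 0.21), FOXQ1 (-4.21 ± 0.30), GBP5 (-4.13 ± 0.19), ZBED10P (-3.95 ± 0.16) and the neuropeptide gene NMU (-3.48 ± 0.11). Adjusted p-values of these genes were 1.69e-08 or lower.

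All 29 G1/S genes (median -1.61, camera adjusted p = 2.52e-18, and adjusted p = 0.0263 with an estimated correlation) and all 28 G2/M genes (median -1.15, 1.43e-16, and adjusted p = 0.0869 with an estimated correlation) fell in siDual. Of 24 EMT genes 19 rose and 2 fell (20 and 2 adjusted over the list alone, 2.89e-06, and adjusted p = 0.0263 with an estimated correlation). Camera also called higher the glycolysis and hypoxia genes (25 of 31 higher and 1 lower, CA9 3.21 ± 0.20, adjusted p = 4.03e-06, and adjusted p = 0.216 with an estimated correlation), YAP and TEAD targets (18 of 23 higher and 1 lower, F3 3.04 ± 0.10, 9.06e-05, and adjusted p = 0.216 with an estimated correlation) and angiogenesis regulators (22 of 37 higher and 9 lower, 0.0146, and adjusted p = 0.104 with an estimated correlation). Wnt response genes (15 of 19 lower and 1 higher, WNT7A -2.49 ± 0.09, adjusted p = 0.000837, and adjusted p = 0.0869 with an estimated correlation) and ribosome biogenesis and MYC targets (24 of 29 lower and 1 higher, 5.89e-06, and adjusted p = 0.216 with an estimated correlation) were called lower. So were the Mullerian and serous lineage factors (8 of 15 lower and 1 higher, 0.0342, and adjusted p = 0.216 with an estimated correlation), but this list holds PAX8 and SOX17 themselves. Without them 6 of 13 were lower and 1 higher, and the call was lost (adjusted p = 0.196, and adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone, these 6 lists had 25 and 1, 18 and 1, 22 and 9, 1 and 15, 1 and 25, and 1 and 8 genes higher and lower. Also called higher were basement membrane, collagen and integrin genes (21 of 31 higher and 5 lower, ITGB6 2.52 ± 0.09, 0.000837, and adjusted p = 0.265 with an estimated correlation) and squamous keratinocyte markers (7 of 9 higher and 1 lower, KRT16 3.51 ± 0.18, 0.0135, and adjusted p = 0.127 with an estimated correlation). Epithelial junction genes (15 of 30 higher and 4 lower, KRT8 2.64 ± 0.11, KRT18 2.64 ± 0.13, 0.0139, and adjusted p = 0.19 with an estimated correlation) were a further such list. Replication-dependent histone genes (9 of 12 higher and 1 lower, 0.04, and adjusted p = 0.477 with an estimated correlation) lost their call against siNT2 alone (adjusted p = 0.08). Ribosomal protein genes were lower (19 of 40 lower and 0 higher, 0.00297, and adjusted p = 0.665 with an estimated correlation). The counts of these 5 lists adjusted over the list alone were 24 and 5, 7 and 1, 15 and 4, 9 and 2, and 0 and 18 higher and lower. The 13 mitochondrially encoded genes rose (median 0.93, adjusted p = 8.73e-06, and adjusted p = 0.355 with an estimated correlation). All genes on the mitochondrial chromosome took 10.6 ± 0.502% of the counts, and ribosomal RNA genes, in part the same genes, 1.49 ± 0.025%.

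The single knockdowns were then compared with each other and with the combination. Between siPAX8 and siSOX17, 3698 genes were higher and 4155 lower in siPAX8. KRT6A (log2 difference 5.20 ± 0.27) and SOX5 (4.74 ± 0.24) were higher and KLHL14 (-5.10 ± 0.18), MAL (-4.19 ± 0.30) and ANKRD2 (-4.11 ± 0.19) lower. IL33 had 1929 counts in siPAX8 against 2 in siSOX17, a ratio of 817 with a counting interval of 226 to 6750. All 28 G2/M genes were lower in siPAX8 than in siSOX17 (28 adjusted over the list alone, median -0.81, camera adjusted p = 5.3e-17, and adjusted p = 0.187 with an estimated correlation). Of the glycolysis and hypoxia genes 26 of 31 were lower and 1 higher (26 and 2 adjusted over the list alone, 4.13e-07, and adjusted p = 0.36 with an estimated correlation). With siDual set against siPAX8, 4115 genes were higher or lower in siDual. The weaker reduction of PAX8 in siDual, given below, is part of this contrast. The 2317 higher ones included SEMA5B (3.08 ± 0.29), GJA5 (2.73 ± 0.22) and ANKRD2 (2.61 ± 0.20), and the 1798 lower ones IL33 (-5.11 ± 0.22) and CXCL5 (-4.50 ± 0.42). With siDual set against siSOX17, 3297 genes were higher or lower in siDual. The 1652 higher ones included IL33, with 50 counts in siDual against 2 in siSOX17 (a ratio of 23.7 with a counting interval of 6.24 to 201, adjusted p = 0.000103), KRT6A (3.08 ± 0.29), A2M (2.82 ± 0.24) and FOXS1 (2.75 ± 0.20), and the 1645 lower ones the crystallin CRYAB, from 461.3 to 50.8 ± 5.73 CPM (-3.19 ± 0.13), MAL (-3.12 ± 0.28) and FGF18 (-2.94 ± 0.16). For siDual versus siPAX8 the 4115 became 2636 and 2701 without siDual replicate 1 and 2 and 2675 without siPAX8 replicate 2. For siDual versus siSOX17 the 3297 became 1822 without siDual replicate 2 and 2081 without siSOX17 replicate 2.

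The combined response was smaller than the sum of the single ones. Of 6713 genes called the same way in siPAX8 and siSOX17, siDual differed from the sum of the 2 log2 fold changes in 4218 genes by being less and in 13 by being more, and 2482 showed no called difference. The median ratio of the siDual change to that sum was 0.573, and to the larger single change 0.967. These genes were chosen by their calls in the same libraries, which favours large single changes and so tilts these values toward less than the sum. Over all genes, without that choice, the slope of siDual on the sum was 0.574. ANGPTL4, at 4.04 ± 0.13 and 5.25 ± 0.12 in the single knockdowns and 5.89 ± 0.12 in siDual, departed from the sum by -3.40 ± 0.18. G1/S genes (29 of 29 above the sum, camera adjusted p = 2.79e-27, and adjusted p = 0.0168 with an estimated correlation) and G2/M genes (28 of 28, 1.61e-28, and adjusted p = 0.0171 with an estimated correlation) departed as lists. So did EMT genes (14 of 24 below the sum, 15 adjusted over the list alone, 5.42e-05, and adjusted p = 0.0171 with an estimated correlation). PAX8 was less reduced in siDual than in siPAX8 (25.3% against 17.4% of the control level, siDual minus siPAX8 0.54 ± 0.09, adjusted p = 0.000124), which bears on any reading of the combination. The labels do not say whether the 120 nM of siRNA in siDual was the total or the amount of each pool.

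**Figure D2:**
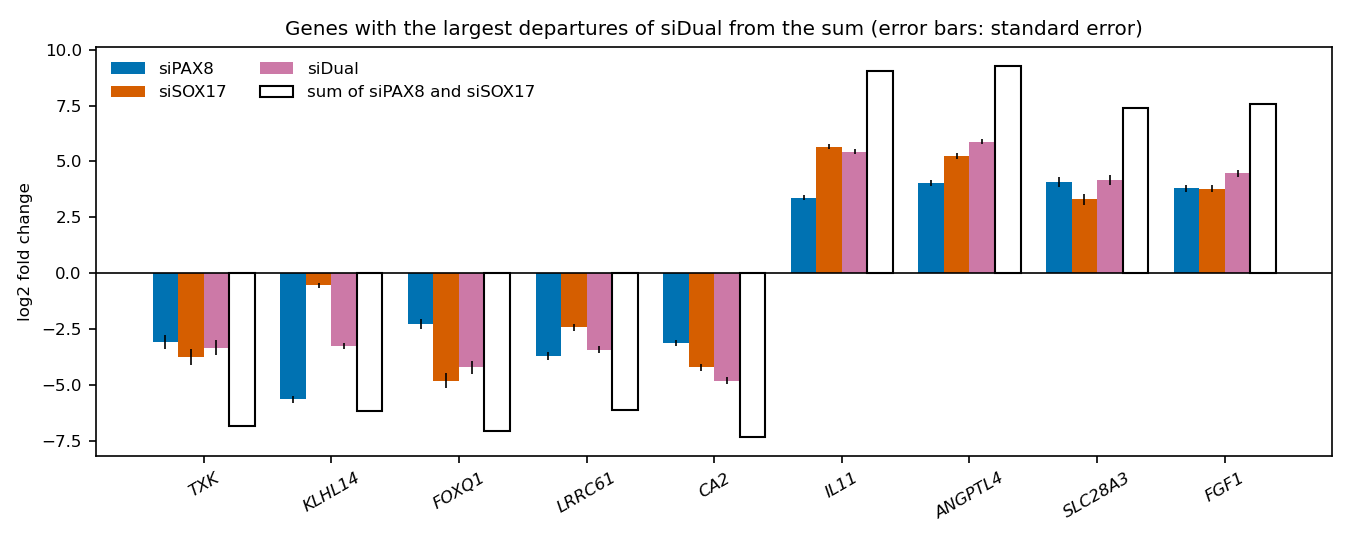
Log2 fold change against the control libraries (vertical axis) of 9 genes among the 10 with the largest departures of siDual from the sum of siPAX8 and siSOX17, with error bars at the standard error and white bars at the sum. The siDual bar of ANGPTL4 (5.89) lies close to the siSOX17 bar (5.25) and below the sum, and that of CA2 (-4.79) lies close to its siSOX17 bar (-4.21).

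In siMECOM 23 of 37 interferon-stimulated genes rose and 2 fell, and of 30 amino acid and unfolded protein stress response genes 23 fell and 1 rose. Camera called both lists, with adjusted p = 0.526 and adjusted p = 0.0752 with an estimated correlation, and no list called in siMECOM kept its call with an estimated correlation. FN1, fibronectin, rose from 1.65 ± 0.264 to 64.5 ± 19.1 CPM (log2 fold change 5.28 ± 0.16). Of 21032 genes 3467 were higher and 3390 lower, and among the 1419 changed by at least 2-fold 968 were higher. PDZK1, a scaffold of epithelial transporters (4.32 ± 0.19), the keratins KRT13 (3.90 ± 0.13) and KRT6A (3.86 ± 0.18), and C6orf15 (3.81 ± 0.15) followed. After these came the oxytocin receptor OXTR (3.62 ± 0.14), LMCD1 (3.24 ± 0.11), SLCO2A1 (3.19 ± 0.17), MYL7 (3.00 ± 0.26) and DCBLD2, from 90.3 ± 5.3 to 693.1 ± 130 CPM (2.94 ± 0.12). The placental alkaline phosphatase ALPP (-4.62 ± 0.28), FAM107A (-3.97 ± 0.18), the target MECOM, lymphotoxin beta (LTB, -3.10 ± 0.30) and TMEM101 (-3.06 ± 0.31) fell most. The interleukin-1 receptor antagonist IL1RN (-3.03 ± 0.30), TAF3 (-2.95 ± 0.11), FOXQ1 (-2.88 ± 0.24), FAM20A (-2.85 ± 0.25) and SLC28A3 (-2.85 ± 0.60) completed the 10. The highest adjusted p among these 20 was 0.00117, for SLC28A3. For siMECOM versus non-targeting the 6857 called genes became 4096 without siMECOM replicate 2, which kept more MECOM than replicate 1.

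SAMD9L (1.11 ± 0.13) was the largest increase among the interferon-stimulated genes in siMECOM (camera adjusted p = 2.81e-05, and adjusted p = 0.526 with an estimated correlation). The cystine transporter SLC7A11 (-1.31 ± 0.15) and the serine synthesis enzyme PSAT1 (-1.28 ± 0.07) were the largest decreases of the amino acid and unfolded protein stress list (1.85e-09, and adjusted p = 0.0752 with an estimated correlation). Of 24 TGF-beta response genes 15 rose and 3 fell, with ID2 at 1.40 ± 0.12 (0.000175, and adjusted p = 0.0752 with an estimated correlation). NF-kB and inflammatory genes fell in 16 of 26 cases and rose in 3, with LTB and IL6 (-2.84 ± 0.21) lower and IL1B higher (2.11 ± 0.24, adjusted p = 0.000511, and adjusted p = 0.688 with an estimated correlation). Glycolysis and hypoxia genes fell in 22 of 31 cases and rose in 1, with VEGFA at -0.96 ± 0.08 (1.68e-05, and adjusted p = 0.523 with an estimated correlation). In the cell cycle lists, 15 of 29 G1/S genes were lower and 1 higher (median -0.23, adjusted p = 0.000175, and adjusted p = 0.523 with an estimated correlation). Of 28 G2/M genes 15 were lower (median -0.22, 4.6e-05, and adjusted p = 0.525 with an estimated correlation). Whether these lists differed from those in siPAX8 or siSOX17 was not tested. Ribosomal protein genes (23 of 40 lower, 7.08e-07, and adjusted p = 0.688 with an estimated correlation) and ribosome biogenesis and MYC targets (12 of 29 lower, 0.000665, and adjusted p = 0.526 with an estimated correlation) were also lower. Wnt response genes (7 of 19 lower and 3 higher, adjusted p = 0.0333, and adjusted p = 0.523 with an estimated correlation) lost their call against siNT2 alone (adjusted p = 0.179). The counts higher and lower of these 10 lists adjusted over the list alone were 24 and 2, 1 and 23, 16 and 3, 3 and 16, 1 and 22, 2 and 19, 0 and 16, 0 and 27, 0 and 13, and 3 and 7. Replication-dependent histone genes rose in 9 of 12 cases (9 adjusted over the list alone, H2AC6 1.44 ± 0.10, 0.000127, and adjusted p = 0.523 with an estimated correlation). Transcripts of this class typically lack a poly(A) tail, which was not tested for these members. All 13 mitochondrially encoded genes rose (median 0.66, 9.48e-07, and adjusted p = 0.526 with an estimated correlation). All genes on the mitochondrial chromosome took 9.14 ± 0.792% of the counts, and ribosomal RNA genes, in part the same genes, 0.95 ± 0.173%.

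The siWT1 pool lowered more genes strongly than it raised, although its target was near the detection floor. GPX3, an extracellular glutathione peroxidase, fell from 246.6 ± 19.1 to 28.0 ± 10.9 CPM (log2 fold change -3.14 ± 0.16), and the tropomyosin TPM4 from 1472 ± 39.5 to 200.1 ± 2.48 CPM (-2.88 ± 0.08). Of 21032 genes 3713 were higher and 4171 lower, and of the 1328 changed by at least 2-fold 465 were higher and 863 lower. The largest decreases were in the Wnt agonist RSPO4 (-3.42 ± 0.19), MALL (-3.40 ± 0.22), GPX3 and the endophilin SH3GL1 (-3.08 ± 0.10). Next were the receptor kinase CSF1R (-3.00 ± 0.22), the chemokine CXCL1 (-2.99 ± 0.28), TPM4, the phosphatidylethanolamine methyltransferase PEMT (-2.86 ± 0.14), SLC2A4RG (-2.78 ± 0.10) and TP53I11 (-2.62 ± 0.11). Acetylcholinesterase (ACHE, 2.76 ± 0.21), the deiodinase DIO2 (2.61 ± 0.17), the MAP kinase phosphatase DUSP4 (2.06 ± 0.19) rose most. NFATC2 (1.86 ± 0.17), COL17A1 (1.84 ± 0.21), LBH (1.79 ± 0.10), the elongation factor EEF1A2 (1.73 ± 0.11), COQ8A (1.68 ± 0.13) and the homeobox gene DLX5 (1.67 ± 0.11) were also among the 10 largest increases. The highest adjusted p of these named genes was 1.75e-06, for COL17A1.

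In siWT1, 12 of 24 EMT genes fell and 0 rose, among them the tropomyosin TPM1 (-2.46 ± 0.09). Camera called this list lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.000327, and adjusted p = 0.102 with an estimated correlation). Basement membrane, collagen and integrin genes fell in 18 of 31 cases and rose in 4 (ITGB3 -2.26 ± 0.09, ITGA3 -1.75 ± 0.14, adjusted p = 0.00208, and adjusted p = 0.345 with an estimated correlation). Cholesterol biosynthesis genes fell in 16 of 25 cases and rose in 3, with the reductase DHCR7 at -1.13 ± 0.08 (0.00048, and adjusted p = 0.345 with an estimated correlation). Fatty acid synthesis genes fell in 9 of 18 and rose in 1 (0.0103, and adjusted p = 0.345 with an estimated correlation). Amino acid and unfolded protein stress response genes fell in 19 of 30 and rose in 2 (0.000269, and adjusted p = 0.345 with an estimated correlation). NF-kB and inflammatory genes fell in 12 of 26 cases, with CXCL8 at -2.21 ± 0.27 (0.00228, and adjusted p = 0.517 with an estimated correlation). G2/M genes fell in 18 of 28 cases and rose in 1 (median -0.21, 0.00228, and adjusted p = 0.345 with an estimated correlation). Of 29 G1/S genes 6 rose and 3 fell, a list that camera did not call (median 0.10, adjusted p = 0.203). Higher lists included nuclear-encoded oxidative phosphorylation genes (20 of 33 higher and 2 lower, SDHD 0.51 ± 0.07, 7.43e-05, and adjusted p = 0.345 with an estimated correlation) and ribosome biogenesis and MYC targets (18 of 29 higher and 3 lower, RCL1 0.74 ± 0.08, 0.000108, and adjusted p = 0.345 with an estimated correlation). Antigen presentation genes were higher too (10 of 17 higher and 2 lower, HLA-B 0.91 ± 0.12, 0.00228, and adjusted p = 0.345 with an estimated correlation). The counts adjusted over the list alone, higher and lower, of the lists after the EMT genes were 4 and 18, 3 and 17, 1 and 9, 4 and 19, 0 and 12, 1 and 19, 6 and 3, 23 and 2, 19 and 3, and 11 and 2. Ribosomal protein genes (6 of 40 higher and 0 lower, 3 and 0 adjusted over the list alone, 0.00853, and adjusted p = 0.633 with an estimated correlation) were called higher too, but not against siNT2 alone. Of the 13 mitochondrially encoded genes 12 rose (median 0.60, 2.3e-05, and adjusted p = 0.345 with an estimated correlation). All genes on the mitochondrial chromosome took 8.60 ± 0.976% of the counts, and ribosomal RNA genes, in part the same genes, 0.768 ± 0.153%.

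The 3' untranslated regions (3' UTRs) of the genes that fell in siWT1 shared a short motif. Of 391 searched genes at least 2-fold lower, 297 (76.0%) held the hexamer CCACAC, against 31.6% of 6165 genes not called and 25.0% of 68 genes at least 2-fold higher. With 3' UTR length, GC content and expression in the model, the odds ratio was 7.18 (95% interval 5.46 to 9.44) for the lower genes and 0.56 (0.29 to 1.08) for the higher ones. Of the 10 largest decreases 9 held the hexamer, with 12 copies in RSPO4, 3 in TPM4 and 0 in CXCL1, and of the 10 largest increases 1 did, NFATC2. The motif was looked for after the response had been seen. It was taken from the heptamer lowest in siWT1 over these same genes, so these shares and odds ratios describe the genes that chose it. A heptamer found on part of the chromosomes is tested on the other part further below.

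**Figure D3:**
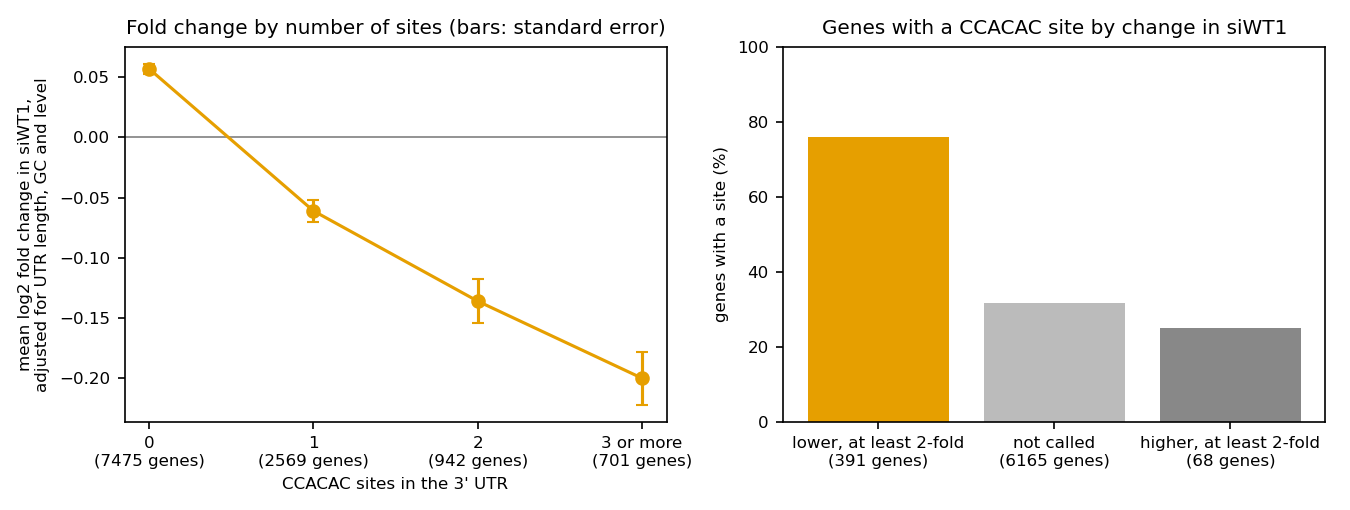
Left, mean log2 fold change in siWT1 adjusted for 3' UTR length, GC content and expression (vertical axis, with standard error) of genes with 0, 1, 2 and 3 or more CCACAC sites in the 3' UTR, which falls from 0.057 to -0.061, -0.136 and -0.20. Right, the percentage of genes with such a site, at 76.0% of the at least 2-fold lower genes, 31.6% of genes not called and 25.0% of the at least 2-fold higher genes.

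The responses to siPAX8 and siSOX17 were correlated, while the correlations of siWT1 with the others were low. Across 21032 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.554 between siPAX8 and siSOX17. Unchanged groups simulated against the same controls gave a mean of 0.313. Those groups hold no response of their own, so the shared controls weigh more in their r than in the real r. Simulated and real r are therefore not on the same scale, and covariances are given for that reason. The covariance exceeded the simulated one by 0.389, and r was 0.496 and 0.48 when the controls were split between the responses. Of the calls, 3478 genes were higher in both against 1536.4 expected of independent lists, 3235 lower in both against 1358.1, and 817 opposite. With the controls split these were 2889 against 1217.4 and 2729 against 1100.6, and 2934 against 1242.1 and 2732 against 1113.5 the other way round. Between siPAX8 and siMECOM r was 0.339 (simulated 0.333, covariance difference 0.156, split controls 0.257 and 0.265). Between siWT1 and the others r lay from 0.021 with siSOX17 to 0.119 with siMECOM (simulated 0.324 and 0.352, covariance differences -0.017 and 0.017). Of the calls in siMECOM and siWT1, 770 were higher in both against 612.1 expected of independent lists, 1210 lower in both against 672.3, and 1205 opposite. With the controls split between them these were 473 against 394.5 and 864 against 496.1 one way round, and 484 against 386.8 and 919 against 479.5 the other. These correlations and overlaps make a family of 10 pairs, of which siPAX8 with siDual (0.811) and siSOX17 with siDual (0.797) were highest.

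**Figure D4:**
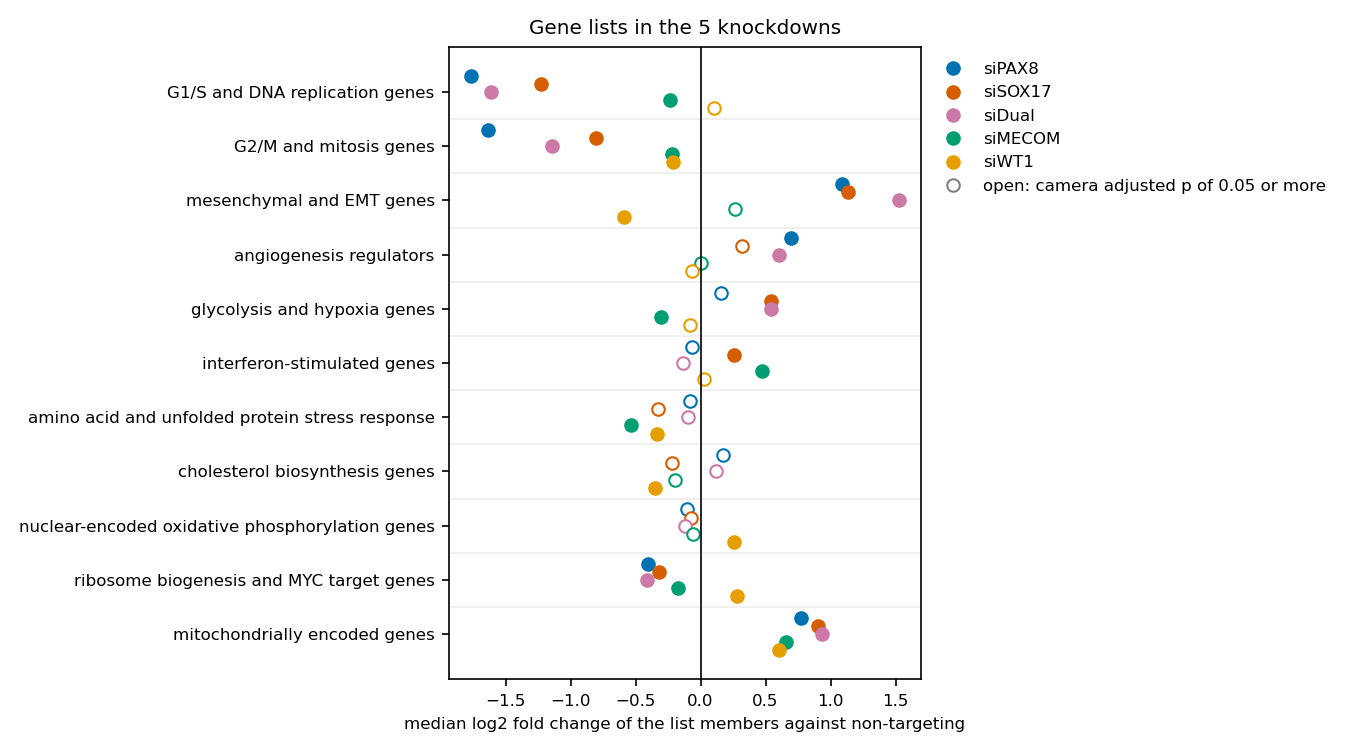
Median log2 fold change against the control libraries (horizontal axis) of the members of 11 gene lists in the 5 knockdowns, with open symbols where the camera adjusted p was 0.05 or more. The G1/S medians lie at -1.77, -1.23 and -1.61 in siPAX8, siSOX17 and siDual, at -0.23 in siMECOM and at 0.10 in siWT1, and the mitochondrially encoded genes lie to the right of 0 in all 5.

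Among the marker lists of other cell types, squamous markers were called higher in siPAX8 and siDual and endothelial markers lower in siSOX17, as given above. Endothelial markers were also lower in siDual than in siPAX8 (4 of 10 lower, 4 adjusted over the list alone, adjusted p = 0.000526, and adjusted p = 0.111 with an estimated correlation) and higher in siPAX8 than in siSOX17 (6 of 10 higher, 7 adjusted over the list alone, 0.00261, and adjusted p = 0.251 with an estimated correlation). Squamous markers were higher in siDual than in siSOX17 (3 of 9 higher, 4 adjusted over the list alone, 0.00866, and adjusted p = 0.131 with an estimated correlation). Against the sum of siPAX8 and siSOX17 they were lower in siDual (4 of 9 lower, 5 lower and 1 higher adjusted over the list alone, 0.0485, and adjusted p = 0.185 with an estimated correlation), a call lost with DESeq2 size factors (0.0521). Camera called none of the fibroblast, leukocyte, neural and multiciliated marker lists in any of the 5 knockdowns, with adjusted p-values in siPAX8 of 0.0881, 0.248, 0.175 and 0.216. In that order 10, 5, 8 and 9 members were tested, at a median log2 CPM of -0.9, -1.35, 0.25 and -1.95. In siPAX8, 6, 2, 1 and 4 of them were higher and 1, 1, 4 and 1 lower. A missing call of such small and low lists does not show that they were unchanged. Mesothelial markers were called lower in siWT1 (5 of 9 lower, LRRN4 -2.51 ± 0.25, camera adjusted p = 0.0247, and adjusted p = 0.345 with an estimated correlation, 1 higher and 6 lower adjusted over the list alone), but this list holds WT1. Without it 4 of 8 were lower, and the call was lost (adjusted p = 0.116, and adjusted p = 0.393 with an estimated correlation). CSF1R, a leukocyte marker that these cells also express (3.85 ± 0.429 CPM in the controls), rose in siPAX8 (2.42 ± 0.13), siSOX17 (2.48 ± 0.13) and siDual (3.13 ± 0.12). FAP, a fibroblast marker, stood at 2 counts in the 4 control libraries together and 33 in siDual, a ratio of 38 with a counting interval of 9.72 to 327.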

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

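In this part, the tests of a guide of the WT1 pool, of a guide of the PAX8 pool and of the mitochondrial transcripts were chosen only after the result was seen.

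A test of the difference itself set apart 5270 genes whose change in siDual departed from the sum of the changes in siPAX8 and siSOX17, along with targeted and most departing genes among them. Departures are given on the log2 scale with the standard error and edgeR's adjusted p, after the changes in siPAX8, siSOX17 and siDual. Among the targeted genes SOX17 (-0.46, -2.942 and -2.717) departed by 0.685 ± 0.149 (adjusted p = 0.00196). MECOM (-0.411, -1.542 and -1.398) departed by 0.556 ± 0.198 (adjusted p = 0.0466), a call lost under 17 alternatives although the size stayed similar. Among these were DESeq2 (0.549, adjusted p = 0.196) and leaving out any 1 of the 12 libraries of the groups other than siMECOM. The departure then lay between 0.503 (without siDual replicate 2) and 0.605 (without siDual replicate 1). The genes above the sum were TXK (-3.088, -3.731 and -3.329) at 3.49 ± 0.666 (adjusted p = 0.000652) and KLHL14 (-5.632, -0.535 and -3.261) at 2.906 ± 0.246 (adjusted p = 9.32e-08). FOXQ1 (-2.267, -4.795 and -4.211) stood at 2.851 ± 0.595 (adjusted p = 0.00142), LRRC61 (-3.688, -2.417 and -3.411) at 2.694 ± 0.265 (adjusted p = 5.02e-07) and CA2 (-3.122, -4.206 and -4.795) at 2.533 ± 0.228 (adjusted p = 1.85e-07). Below the sum, IL11 (3.384, 5.656 and 5.438) stood at -3.602 ± 0.161 (adjusted p = 5.62e-11). ANGPTL4 (4.037, 5.248 and 5.886) stood at -3.399 ± 0.178 (adjusted p = 4.3e-10), SLC28A3 (4.097, 3.307 and 4.184) at -3.221 ± 0.325 (adjusted p = 6.89e-07) and FGF1 (3.797, 3.789 and 4.464) at -3.122 ± 0.239 (adjusted p = 2.8e-08).

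The siWT1 pool changed many genes although WT1 had 75 counts over the 4 control libraries. A response common to all targeting pools is argued against as the whole cause. With the controls split, the covariance of siWT1 with siMECOM was 0.0375 of the variance of the siWT1 changes, under the bound of 0.1 set beforehand. A smaller shared part is not excluded. With the controls split, 864 genes were lower in both groups against 496.1 expected of independent lists, and 919 against 479.5 the other way round. Higher in both were 473 against 394.5 and 484 against 386.8. A guide of the WT1 pool pairing through its seed, the bases with which a guide finds partly matching transcripts, may account for part of the decreases: CCACACT, the heptamer lowest in siWT1 on each part of the chromosomes, was over-represented among the genes at least 2-fold lower on the other part, with odds ratios of 7.05 (95% interval 4.95 to 10.05) and 5.65 (4.03 to 7.93), and its t was -19.66 in siWT1 (lowest of permuted genes -5.54) and 0.78 to 1.63 in the other knockdowns. Of the 10 lowest heptamers 6 lie in the WT1 mRNA against 2.0 expected (one-sided exact binomial p = 0.00644), but 7 lie in the MECOM mRNA (p = 0.03). These p-values take the 10 heptamers as independent, while 7 of them hold the same hexamer CCACAC, so neither can be taken at face value. CCACACT itself lies in the MECOM and not in the WT1 mRNA, so that a guide matching WT1 would pair with its sites through 6 bases. Loss of the little WT1 present, the biological explanation the design gives, stays open and was not tested.

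The other pools were searched in the same way for decreases that follow seed matches. Here too the binomial p-values take the 10 lowest heptamers as independent, although several overlap in sequence, so they overstate the evidence. In siPAX8, 3 of the 10 lowest heptamers lie in the PAX8 mRNA against 2.08 expected (one-sided exact binomial p = 0.347). This test, set before the search but after the gene comparisons had been seen, thus did not pass. However, GCCAGCT, which lies in the PAX8, SOX17 and MECOM mRNAs, had a t of -10.56 in siPAX8, -5.99 in siDual and -0.05 in siSOX17. Its odds ratios on the chromosomes left out were 2.45 (95% interval 1.75 to 3.42) and 2.85 (2.12 to 3.84). A guide of the PAX8 pool pairing through its seed may account for some of the decreases. For siDual 6 of 10 lie in the PAX8 or SOX17 mRNA against 2.96 expected (exact p = 0.0447), but the lowest of them is TTTTTTA (t -6.48), so the T-rich trend described next stays open there too. In siSOX17 the 7 of 10 in the SOX17 mRNA (exact p = 3.97e-05) cannot be told apart from a trend in T-rich 3' UTRs, since TTTTTTA had the lowest t (-8.06) and the PAX8 (6, p = 0.00784) and WT1 (7, p = 0.000876) mRNAs hold as many or nearly as many, and in siMECOM 3 of 10 against 3.59 expected (p = 0.757) leave seed matches open. Loss of each targeted factor, the biological explanation, also stays open for these decreases.

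Mitochondrially encoded transcripts were higher in all 5 knockdowns than in the controls. An effect of the scaling alone is argued against. Before any scaling the genes of the mitochondrial chromosome took at least 7.91% of the counts in each of the 10 knockdown libraries. In the 4 control libraries they took at most 6.13%. A share of the counts also rises where other RNA falls, which these values do not address. More RNA without a poly(A) tail was judged by the histone transcripts. Whether the measured histone transcripts lacked the tail, and whether mitochondrial transcripts follow them in this, was not tested, so these values cannot decide it. In siWT1 the histone transcripts changed by a mean of -0.348 ± 0.088 against a mitochondrial median of 0.603. That standard error is over 12 genes, which are not independent replicates. In siPAX8, siSOX17, siDual and siMECOM the lowest histone median was 0.896. Camera called the histone list in siDual (adjusted p = 0.04, and adjusted p = 0.477 with an estimated correlation) and siMECOM (adjusted p = 0.000127, and adjusted p = 0.523 with an estimated correlation). In siPAX8 (adjusted p = 0.108) and siSOX17 (adjusted p = 0.0608) it did so only with a replicate block (adjusted p = 0.019 and 0.01). Fewer dividing cells in the knockdown cultures cannot be told apart from the other sources, since the G1/S median was 0.103 in siWT1 while its G2/M median was -0.209, and an effect of the knockdowns on mitochondrial transcripts stays open and was not tested.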

How the results depend on the processing

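All alternatives named were planned except the fit without mitochondrially encoded genes and the lists without the targeted genes, which were chosen after seeing the data, and all planned ones were run. Of the values of named genes, 1189 of 1193 kept direction and call with DESeq2 size factors and 1178 of 1193 without a filter. With DESeq2 at most 1133 of 1193 did, since values to which it gave no adjusted p were counted as kept unless reversed. Also kept were 1058 of the 1060 that passed the stricter filter, 1193 of 1193 with a replicate block and 816 of 822 with the controls as 1 group. Against siNT1 or siNT2 alone 770 and 764 of 822 were kept, and without mitochondrial genes 1168 of 1177. With 1 library left out 16038 of 16702 were kept, a total that includes fits without a library outside the comparison. The values that reversed were ANKRD1: siSOX17 versus non-targeting (-0.233, and 0.001 against siNT2 alone), and with 1 library left out DCN: siPAX8 versus non-targeting (-5.272 to 5.073), DCN: siPAX8 versus siSOX17 (-3.379 to 7.587), each lowest without siPAX8 replicate 1, and CLDN5: siDual against the sum of siPAX8 and siSOX17 (-1.781 to 4.289, lowest without siDual replicate 2). Requiring a 2-fold change left 3051 genes in siPAX8, 3069 in siSOX17, 3539 in siDual, 1419 in siMECOM, 1328 in siWT1, 10 between the control pools, 829 and 741 for siDual versus siPAX8 and siDual versus siSOX17, and 2047 for siPAX8 versus siSOX17, by construction. The 63 genes of siNT1 versus siNT2 became 232 without a filter, 150 with the replicate block, 157 with DESeq2 and 11 to 77 with 1 library left out. Leaving out 1 library gave 4096 to 7044 genes for siMECOM versus non-targeting, 2636 to 4220 for siDual versus siPAX8 and 1822 to 3355 for siDual versus siSOX17. With only the groups compared, 10733 genes were called for siPAX8 versus non-targeting, 10847 for siSOX17 versus non-targeting, 11703 for siDual versus non-targeting, 7032 for siMECOM versus non-targeting, 7650 for siWT1 versus non-targeting and 64 for siNT1 versus siNT2. In the fits with 1 library left out the lone library is taken to vary like the other groups, and fewer libraries were compared. Lists called fell with an estimated correlation to 4 in siPAX8, 2 in siSOX17, 2 in siDual, 5 against the sum and 0 in siMECOM, siWT1, siNT1 versus siNT2 and the comparisons between siPAX8, siSOX17 and siDual. With fry, which asks another question, they numbered 28, 33 and 29 in siPAX8, siSOX17 and siDual, 26 in siWT1, 0 in siNT1 versus siNT2, 15 and 14 for siDual versus siPAX8 and siSOX17, and 25 for siPAX8 versus siSOX17, and with the replicate block 4 in siNT1 versus siNT2. Correlations with siWT1 with the controls split both ways and over genes with a mean log2 CPM of at least 3 were 0.014, 0.014 and 0.019 for siPAX8, -0.047, -0.033 and -0.038 for siSOX17, and -0.012, 0 and -0.001 for siDual, and for siMECOM 0.033 and 0.024 with the controls split. Splitting removes the shared control libraries by construction, and the cause of the other changes was not tested. Depth limits the genes at low counts, WT1 among them.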

Other observations

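In this part, the test of the siNT2 pool and the list tests without targeted genes were chosen only after the result was seen.

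Markers of high-grade serous carcinoma and Mullerian secretory cells changed without a common direction. Of 22 measured, 11 rose and 7 fell in siPAX8 (11 and 8 adjusted over the list alone, camera adjusted p = 0.248), 10 rose and 9 fell in siSOX17 (10 and 9, 0.589) and 11 rose and 9 fell in siDual (11 and 9, 0.777). In siMECOM 5 rose and 11 fell (5 and 11, 0.414), as in siWT1 (5 and 12, 0.15). The kallikrein proteases KLK5 (log2 fold changes 2.77 ± 0.17, 3.34 ± 0.17 and 4.45 ± 0.17) and KLK6 (1.54 ± 0.09, 1.79 ± 0.09 and 1.99 ± 0.09) rose in siPAX8, siSOX17 and siDual. The kidney cadherin CDH6 fell in siPAX8 (-1.58 ± 0.08), siSOX17 (-1.78 ± 0.08), siDual (-2.86 ± 0.09) and siWT1 (-1.38 ± 0.08) and rose in siMECOM (1.83 ± 0.07). In siMECOM the mucin MUC1 (-2.83 ± 0.19) and the secreted marker WFDC2, or HE4 (-1.13 ± 0.11), fell. Osteopontin (SPP1) rose in siMECOM (1.79 ± 0.08) and fell in siWT1 (-1.47 ± 0.09).

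Of 15 Mullerian and serous lineage factors, 7 fell and 1 rose in siPAX8 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0919) and 9 fell and 4 rose in siSOX17 (9 and 4, 0.187). The targeted gene is counted in each, and without it 6 of 14 fell in siPAX8 (0.186) and 8 of 14 in siSOX17 (0.336). Among 11 genes known as PAX8 targets in thyroid and kidney, 5 fell and 3 rose in siPAX8 (5 and 3 adjusted over the list alone, camera adjusted p = 0.364). The kidney cadherin CDH16 fell in siPAX8 (-2.51 ± 0.35), siMECOM (-3.29 ± 0.38) and siWT1 (-2.46 ± 0.33) and rose in siSOX17 (2.12 ± 0.21), and the thyrotropin receptor TSHR rose in siMECOM (2.94 ± 0.20). Of 15 genes of the RNA interference machinery, 6 rose and 5 fell in siPAX8 (6 and 5 adjusted over the list alone, camera adjusted p = 0.994), where AGO1, which binds small RNAs, fell (-1.63 ± 0.10) and DICER1 rose (0.81 ± 0.08). AGO1 also fell in siDual (-1.54 ± 0.10).

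A guide of the siNT2 pool pairing through its seed may lower some genes in siNT2. The heptamer TTGCTCA had the highest t in siNT1 minus siNT2 (12.8, highest of permuted genes 5.1). Genes with it were higher in siNT1 by 0.058 (95% interval 0.045 to 0.071) and 0.057 (0.045 to 0.069) on the log2 scale, each on the chromosomes not used to find it. The guide sequences are not given, so the match itself was not tested.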
